A study of Homo sapiens with 6 samples.

How the data were processed

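RNA sequencing libraries of MIA-PaCa2 and PANC-1 cells with the LPCX control, ESRP1 or ESRP2 were analysed, 1 library for each of the 6 combinations. Per the labels, cells were grown in medium with 10% fetal bovine serum, and libraries were made from 2 ug of total RNA with a TruSeq mRNA kit. Per the submitters' processing notes, Salmon was used with GRCh38 (hg38). The versions of Salmon, of the annotation and of any other upstream step are not given in the sources used here. The authors deposited 1 table of TPM, abundances scaled for transcript length and library size, for RefSeq transcripts, with 67792 lines, of which 8664 repeat another transcript with identical values. Because of the repeats, a deposited column sums to more than 1000000, and the repeats were removed first. After that 59128 transcripts remained (45460 NM and 13668 NR accessions) in 27408 genes, and each library summed to 1000000. TPM keeps no record of the number of reads, so the depth is unknown, and no counting intervals are given.

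Columns were matched to samples by cell line and construct. The column for ESRP2 in MIA-PaCa2 is headed with ESRP12, and that for LPCX in MIA-PaCa2 spells the line differently. Both were assigned by elimination, and the ESRP1 and ESRP2 levels in the 6 libraries fit this assignment. The headers of both LPCX columns end in N and those of the ESRP columns in T, which is not explained. TPM were summed per gene symbol and used as deposited. Median ratio scaling served as an alternative, with log2 factors between -0.05 and 0.06.

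Within a line, log2 ratios of TPM plus 1 were taken between each ESRP library and the LPCX library of that line, for genes with at least 5 TPM in either, and counted from 2-fold. There are no replicates, so no p-value is attached. Counts in both lines were set beside those for independent lines, the product of the counts per line divided by the number of genes. Over both lines, limma with a trend was fitted to log2 of TPM plus 1 for 11829 genes with at least 5 TPM in at least 2 libraries, with construct and cell line as terms. This leaves 2 residual degrees of freedom, and the spread is the difference of a construct's effect between the lines. The cell line is the block of this design. P-values were adjusted by Benjamini-Hochberg at 0.05 per contrast. The count models planned for read counts do not apply to TPM and were left out. The model was tested on simulated values with 200 known changes per run.

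Transcript shares were computed for genes with at least 2 transcripts and at least 5 TPM in every library, for transcripts with at least 10% in a library. The same limma model was fitted to log2 odds of a transcript within its gene with a pseudocount of 0.5 TPM. A share was counted as moved from 10 percentage points. Enrichment of fixed lists among genes with moved shares used Fisher's exact test, two-sided, with the 6003 genes that could have been counted as background and adjustment over lists. RefSeq transcripts were paired with GENCODE release 29 transcripts on GRCh38, 38658 in all (65.4% of transcripts and at least 80.4% of the TPM of a library). Inclusion of a cassette exon is the TPM of paired transcripts that hold the exon, as a percentage of those and of paired transcripts that span and skip it. Exons were kept where the gene and the transcripts around the exon had at least 5 TPM and paired transcripts at least 90% of the gene in every library, and where inclusion reached 5% in some library and was 95% or less in some library. The step and the cassette exons were chosen after the data were opened. Shares come from the authors' quantification, which splits reads between overlapping transcripts, and junction reads were not used here.

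Before the data were examined 29 gene lists were fixed, of epithelial junction and identity, mesenchymal and EMT, ESRP-regulated splicing targets, splicing factors, cell cycle phases, signalling and stress responses, metabolism, pancreatic cancer subtypes, and markers of leukocytes, acinar and islet cells, fibroblasts and endothelium, and neurons. Over both lines 26 lists with at least 3 measured members were tested with camera of limma at a correlation of 0.01 between genes, and again with an estimated correlation. Members were also counted when adjusted over the list alone. Within a line the median ratio of a list was placed among 10000 random lists of equal size matched on expression (seed 20), as a description. Symbols that differ between the lists and the table, mostly histones, were matched through Ensembl identifiers, a step added after the data were examined. The 8 list calls were the same before and after this step.

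Named genes followed a rule fixed beforehand. It took ESRP1, ESRP2, CDH1, EPCAM, VIM, ZEB1, FGFR2, CD44, CTNND1 and ENAH; for each construct the 10 highest and 10 lowest genes by the smaller ratio of the 2 lines; 5 more per direction, line and construct; 5 per direction for ESRP1 against ESRP2; up to 5 called genes per direction; and up to 4 members of each list by mean absolute ratio. Genes without a symbol were left out of the ranking. The rule gave mostly small RNA entries, so it was also run on genes with an NM transcript after the data were seen. Exons, transcripts and the remaining genes named in the text were chosen after their values were seen.

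The responses to ESRP1 and ESRP2 within a line share an LPCX library, so their correlation was set beside that simulated for unchanged groups with a shared control. Alternatives covered the pseudocount, the floor, the fold, scaling, the filter, the block, each library left out, the correlation of list tests, and for isoforms the gene total, the step and the pseudocount. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.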

Results

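Messenger RNA was profiled by RNA sequencing in MIA-PaCa2 and PANC-1, established human pancreatic cancer cell lines. Each line was studied in 3 forms, carrying the control construct named LPCX in the labels, overexpressing ESRP1, or overexpressing ESRP2. ESRP1 and ESRP2 are epithelial splicing regulatory proteins, RNA-binding paralogs that steer exon choice in epithelial cells, and the labels state that their function in pancreatic cancer was the question. There were 6 libraries, 1 for each line and construct, so no comparison within a line has replicates. The values are the deposited TPM, abundances scaled for transcript length and library size, of 59128 RefSeq transcripts in 27408 genes, and the number of reads behind them is unknown. Between 10578 and 10932 genes reached 5 TPM per library, and the 10 most abundant genes took 10.8% to 13.7% of the TPM. Transcripts with no coding sequence (NR accessions) took 12.97% of the TPM in PANC-1 LPCX, against 9.82% in PANC-1 ESRP1 and 10.1% in PANC-1 ESRP2. In MIA-PaCa2 their share was 11.1% with LPCX, 9.39% with ESRP1 and 12.1% with ESRP2. The microRNA entries MIR4461 and MIR6723 together took 7.002%, 4.66% and 5.195% of the TPM in PANC-1 with LPCX, ESRP1 and ESRP2. In MIA-PaCa2 they took 5.602%, 4.605% and 6.28%. Most of each difference from LPCX in the NR share lay in these entries. The NR shares therefore do not show a broad difference in noncoding RNA.

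The introduced genes were read out first. ESRP1 was at 0.0781 TPM in MIA-PaCa2 LPCX and 0.261 TPM in PANC-1 LPCX, and at 367 and 491 TPM in the corresponding ESRP1 libraries. Nearly all of it was assigned to the transcript NM_017697. ESRP2 was at 0.0704 TPM in MIA-PaCa2 LPCX and 197 TPM in MIA-PaCa2 ESRP2. PANC-1 already held 34.8 TPM of ESRP2 with LPCX, which became 308 TPM in PANC-1 ESRP2. The construct for one paralog left the other near its LPCX level, with ESRP2 at 0.106 and 37.7 TPM in the ESRP1 libraries and ESRP1 at 0.125 and 0.172 TPM in the ESRP2 libraries of MIA-PaCa2 and PANC-1.

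**Figure D1:**
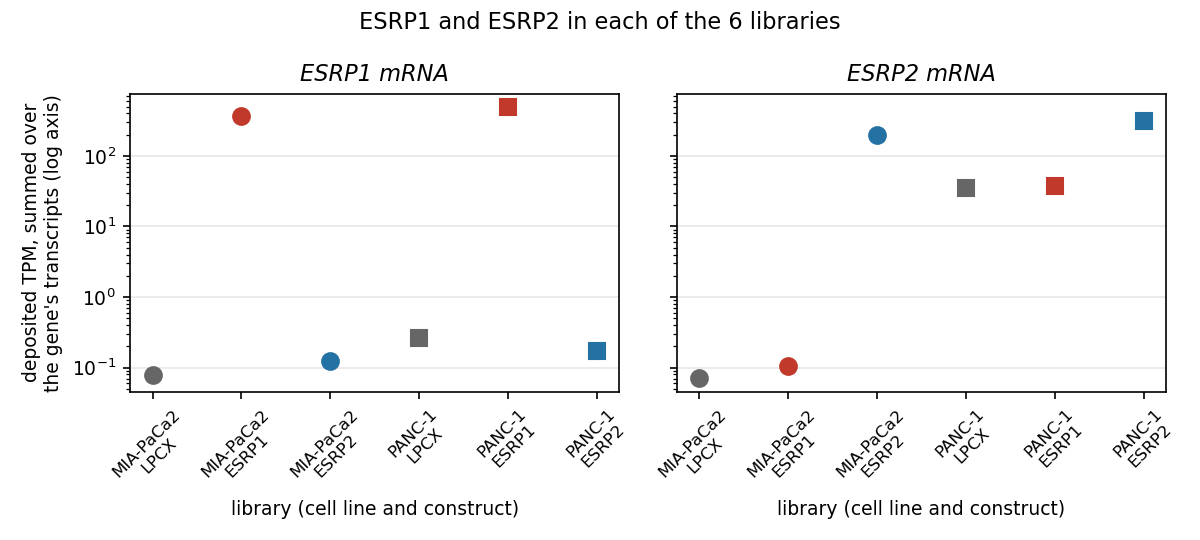
Deposited TPM of ESRP1 and ESRP2 (log axis) in each of the 6 libraries, with 1 point per library, circles for MIA-PaCa2 and squares for PANC-1. ESRP1 is at 367 and 491 TPM in the ESRP1 libraries and at most 0.261 TPM in the others, and PANC-1 holds ESRP2 at 34.8 TPM before overexpression.

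The first question was which isoforms changed with either protein. CD44, the cell-surface receptor for hyaluronan, moved from its short form to forms with variable exons in all 4 comparisons. NM_001001391, which lacks the variable exons, made up 81.4% of CD44 TPM in MIA-PaCa2 LPCX, 14.97% with ESRP1 and 26.3% with ESRP2. In PANC-1 the same transcript had 81.1% with LPCX, 15.98% with ESRP1 and 27.04% with ESRP2. NM_001001390, with 3 variable exons, had 0.280%, 42.8% and 44.1% in MIA-PaCa2 and 7.13%, 40.9% and 41.6% in PANC-1, in the order LPCX, ESRP1, ESRP2. Total CD44 differed little from LPCX, with log2 ratios of 0.04 for ESRP1 and -0.10 for ESRP2 in MIA-PaCa2 and of 0.23 and 0.17 in PANC-1. The 3 exons lie on chromosome 11 of GRCh38 at 35208105 to 35208206, 35209965 to 35210054 and 35211246 to 35211449, and all are coding. Inclusion of the first was 3.67%, 72.6% and 64.0% in MIA-PaCa2 and 12.05%, 80.9% and 70.1% in PANC-1. Across 12965 transcripts of 6003 genes tested with limma over both lines, NM_001001391 was the 1 transcript called for ESRP1, with log2 odds of -4.56 (SE 0.201, 2 lines, adjusted p = 0.0433). For ESRP2 its log2 odds were -3.57 (SE 0.201, adjusted p = 0.0753), and limma called 0 transcripts with 824 at an unadjusted p under 0.05. The ESRP1 call ended when any 1 of the 6 libraries was left out, with 0 transcripts called each time.

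**Figure D2:**
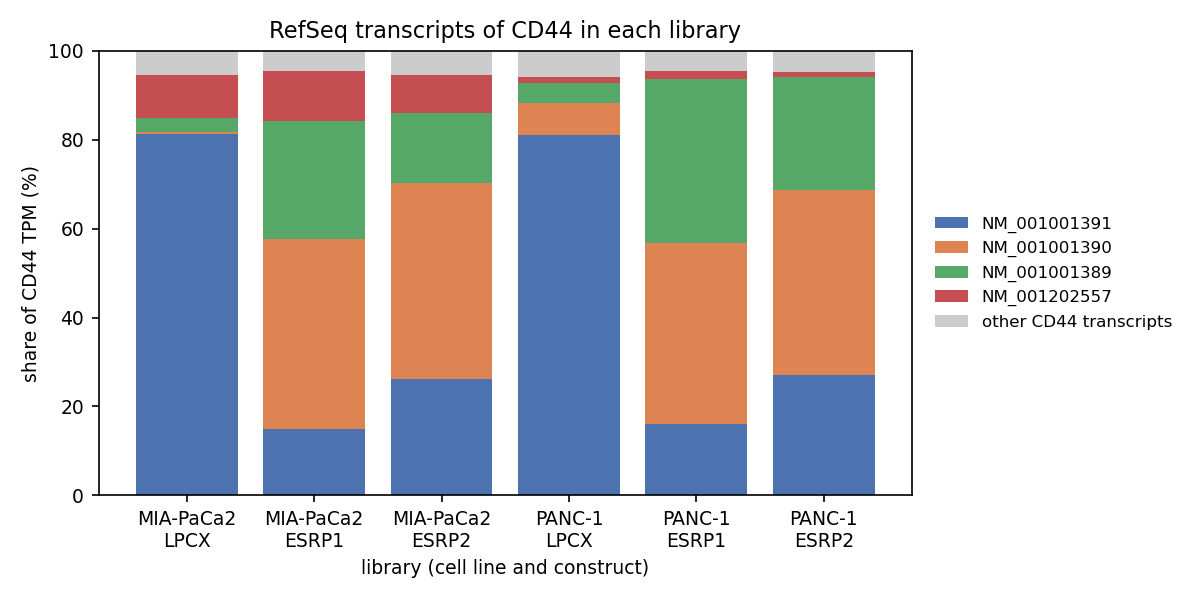
Share of CD44 TPM (%) taken by each RefSeq transcript in the 6 libraries, as stacked bars, with transcripts under 5% in every library pooled. NM_001001391 is at 81.4% and 81.1% with LPCX and between 14.97% and 27.04% with ESRP1 or ESRP2.

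Exons of other genes, named here after their values were seen, were placed differently from LPCX in the same way in all 4 comparisons. ENAH, an actin regulator, included a 63-nucleotide coding exon (chromosome 1, 225504991 to 225505053) at 2.395% in MIA-PaCa2 LPCX, 65.6% with ESRP1 and 57.1% with ESRP2. In PANC-1 the ENAH exon was at 4.45%, 41.2% and 27.9%. The kinase SLK included a 93-nucleotide exon (chromosome 10, 104010816 to 104010908) at 0.827%, 45.6% and 43.7% in MIA-PaCa2 with LPCX, ESRP1 and ESRP2, and in PANC-1 at 0.9994%, 17.8% and 15.7%. DNM2, the endocytic GTPase dynamin, included a 12-nucleotide exon (chromosome 19, 10808569 to 10808580) at 15.3%, 48.9% and 74.0%, and in PANC-1 at 67.1%, 86.3% and 89.97%. Inclusion was lower in OSBPL3, an oxysterol-binding protein relative, and in MYOF, the membrane repair protein myoferlin. The OSBPL3 exon (chromosome 7, 24863200 to 24863292) was at 95.9%, 71.8% and 71.1% in MIA-PaCa2 and 82.2%, 65.2% and 59.5% in PANC-1. The MYOF exon (chromosome 10, 93392917 to 93392955) was at 96.5%, 82.2% and 65.1%, and in PANC-1 at 97.0%, 82.1% and 65.7%.

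**Figure D3:**
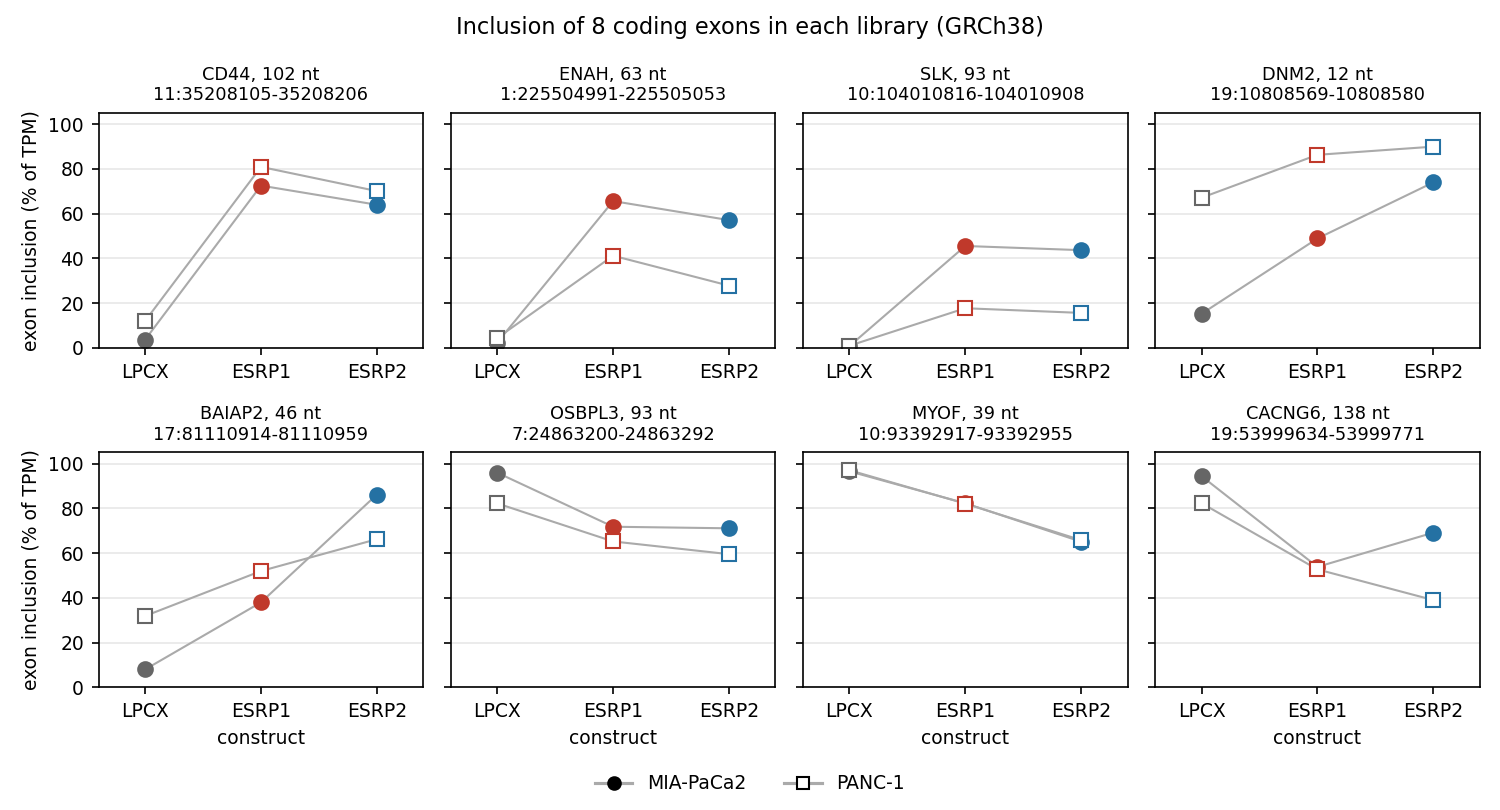
Inclusion of 8 coding exons (% of the TPM of paired transcripts) under LPCX, ESRP1 and ESRP2, with filled circles for MIA-PaCa2 and open squares for PANC-1, 1 library per point. Inclusion is higher than with LPCX in CD44, ENAH, SLK, DNM2 and BAIAP2 and lower in OSBPL3, MYOF and CACNG6, in both lines and with both proteins.

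Among 2146 cassette exons in 1426 genes, 28 exons in 18 genes moved by at least 10 percentage points in the same direction in all 4 comparisons, 22 toward inclusion and 6 toward skipping. With the shared LPCX library kept within each line, independent lines would give 1.92 and 0.830. Besides those above, inclusion was higher for exons of the Golgi tether USO1, the membrane scaffold BAIAP2, FNIP1, the growth factor gene PDGFA, the DNA methyltransferase DNMT3B and TRAPPC6A, and for an untranslated exon of LRRC14. BAIAP2 (chromosome 17, 81110914 to 81110959, coding) was at 7.97%, 38.0% and 86.1% in MIA-PaCa2 and 31.9%, 52.0% and 66.2% in PANC-1. Inclusion was lower for exons of the calcium channel subunit CACNG6, the cadherin CDH24, ARHGAP17 and ZDHHC7. With ESRP1, 34 exons were higher and 15 lower by the step in both lines, against 5.85 and 4.25 for independent lines. With ESRP2 the counts were 49 and 22, against 8.40 and 4.64. Opposite moves numbered 18 for ESRP1 (9.97 for independent lines) and 11 for ESRP2 (12.5). At a step of 20 points, 13 exons were higher and 1 lower with ESRP1, 15 higher and 5 lower with ESRP2, and 0 moved in opposite directions. These counts compare single libraries, so they carry no p-value, and neighbouring exons of 1 gene are not independent.

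**Figure D4:**
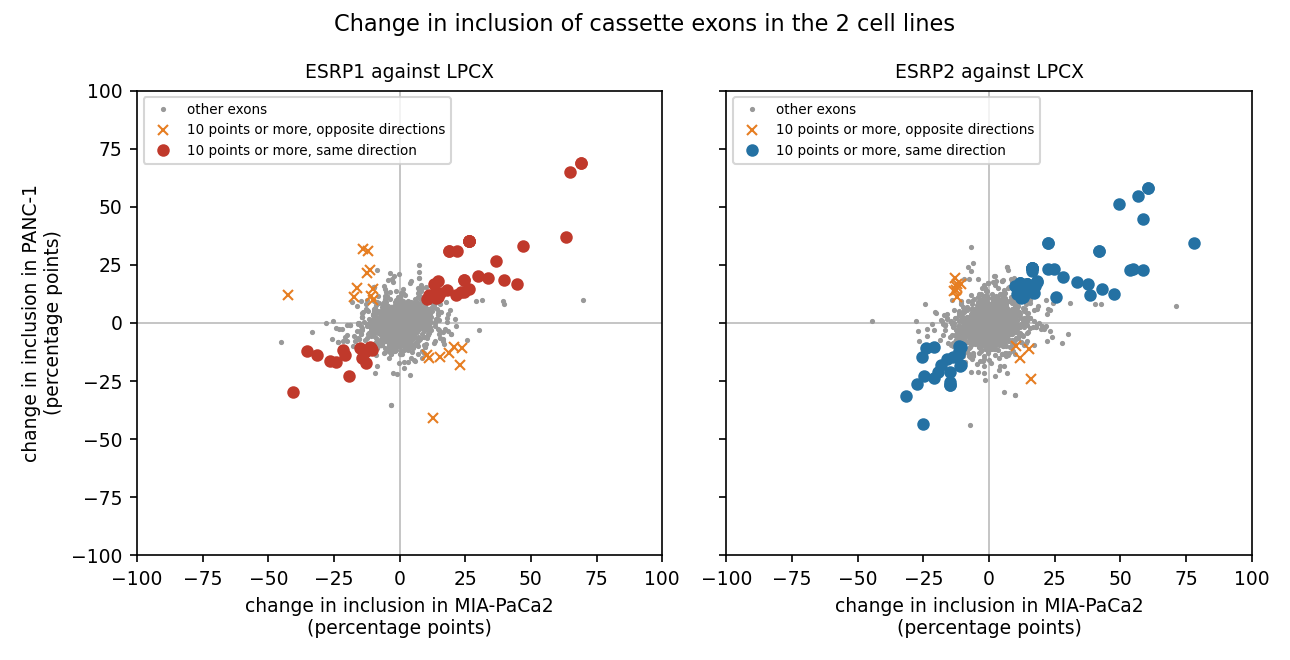
Change in inclusion against LPCX (percentage points) of 2146 cassette exons in MIA-PaCa2 (horizontal axis) and PANC-1 (vertical axis), for ESRP1 and ESRP2, with 1 point per exon. Filled points moved by at least 10 points in the same direction in both lines (49 exons for ESRP1 and 71 for ESRP2), crosses in opposite directions (18 and 11).

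Genes fixed beforehand as ESRP splicing targets led the isoform changes. Transcript shares moved by at least 10 points in the same direction in both lines in 11 of 26 measured targets with ESRP1 and in 157 of 6003 genes (odds ratio 29.3, Fisher's exact test, adjusted p = 3.04e-10). With ESRP2 this held for 14 of 26 targets and 216 of 6003 genes (odds ratio 33.4, adjusted p = 5.30e-13). In all 4 comparisons it held for 10 of 26 targets and 55 genes (odds ratio 82.4, adjusted p = 1.68e-13). No other fixed list passed this test, the closest being 2 of 6 NF-kB, cytokine and chemokine genes with ESRP1 (adjusted p = 0.0951). The test takes genes as independent and rests on single libraries, so its p-values do not measure the spread between libraries. The targets had 88 transcripts in 26 genes and the background 12965 in 6003. Genes with more transcripts have more ways to be counted, which was not adjusted for. CTNND1, the catenin that binds the tails of cadherins, had its transcript NM_001085460 at 41.4%, 11.2% and 18.2% in MIA-PaCa2 and 33.0%, 5.09% and 12.2% in PANC-1. Genes outside the list, named after their values were seen, included CYB561A3, TUFT1, UAP1, EPB41L5, MYO18A, VPS29, TRIM16 and MUC1. UAP1, an enzyme of amino sugar synthesis, had NM_003115 at 74.8%, 13.1% and 15.7% in MIA-PaCa2 and 16.9%, 0.169% and 3.02% in PANC-1. Of the 88 transcripts of the targets, limma called 25 in 13 genes for ESRP1 and 30 in 16 genes for ESRP2 when adjusted over the list alone, against 1 and 0 when adjusted over all transcripts. APLP2, CD44, CTNND1, DNM2, ENAH, ITGA6, NF2, OSBPL3, PLEKHA1, SLK and TCF7L2 were among the genes for ESRP1. For ESRP2 the set lacked APLP2 and also held KIF13A, MAP3K7, MBNL1 and RAC1. Over all transcripts, 123 moved up and 113 down by the step in both lines with ESRP1 (46.5 and 43.8 for independent lines), and 165 and 146 with ESRP2 (61.1 and 54.2). Opposite moves were also above independence, at 188 (90.3) and 208 (115). Part of these counts may thus come from transcripts that vary in any direction, which was not tested.

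ESRP1 against LPCX over both lines gave modest changes in gene level. Most genes lay slightly above LPCX, with 68.3% of 11829 positive and a median log2 change of 0.06. TPM sum to the same total in each library, so such a shift does not show a general rise in level. The log2 median ratio factors were likewise higher with ESRP1 than with LPCX. They were -0.02 against -0.05 in MIA-PaCa2 and 0.05 against -0.02 in PANC-1. Cholesterol synthesis genes were positive in 22 of 24, with a median of 0.22. Among them HMGCS1, an early enzyme of the pathway, was at 0.27 in MIA-PaCa2 and 0.51 in PANC-1, and MVK, mevalonate kinase, at 0.51 and 0.24. The genes of the ESRP splicing target list were positive in 34 of 34 (median 0.13), and the G1/S genes in 37 of 40 (median 0.13), with UNG, which removes uracil from DNA, at 0.38 and 0.45. Epithelial junction and identity genes were positive in 22 of 29 (median 0.11), led by the epithelial transcription factor GRHL1 at 1.22 in MIA-PaCa2 and 0.72 in PANC-1. Hypoxia and glycolysis genes were positive in 30 of 34 (median 0.12), with the aldolase ALDOC at 0.48 and 0.44 and lactate dehydrogenase LDHA at 0.15 and 0.31. In camera these 5 of 26 lists passed, at adjusted p = 1.51e-05 for cholesterol, 0.000378 for splicing targets, 0.00223 for G1/S and 0.0365 for both epithelial and hypoxia genes. None held when the correlation was estimated from the data, at adjusted p = 0.918 with an estimated correlation for each of the 5. That version rests on 2 residual degrees of freedom and can hardly pass a list. The epithelial list had an estimated correlation of -0.0268, below the fixed 0.01, yet its camera p went from 0.00598 to 0.0897. The other called lists had estimated correlations of 0.199 to 0.721. The loss therefore does not show that correlation between members made these calls. By line, the hypoxia genes had medians of 0.06 in MIA-PaCa2 and 0.19 in PANC-1 (percentiles 68.4 and 99.96 of random lists), and the G1/S genes 0.06 and 0.21 (percentiles 77.6 and 100). Across genes the ESRP1 ratios also increased with transcript length, by a rank correlation of 0.0590 in MIA-PaCa2 and 0.231 in PANC-1.

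Single genes rarely passed the test for ESRP1. Over 11829 genes limma called ESRP1 itself, with a log2 change of 8.51 (SE 0.130, 2 lines, adjusted p = 5.36e-05), and 0 genes lower, with 820 genes at an unadjusted p under 0.05. Adjusted over the list alone, GRHL1 (0.97, SE 0.151) and the Arf GTPase activator ARFGAP2 (0.41, SE 0.0700) rose among the splicing targets, and GRHL1 among the epithelial genes. The lists otherwise held 0 genes called in either adjustment. The named-gene rule gave mostly small RNA entries, so it was also applied to genes with a coding transcript, a step added after the data were seen. Of these, CCNJ was at 0.46 and 0.48, the kinase HIPK3 at 0.48 and 0.45, the stress cytokine GDF15 at 0.45 and 0.46, and CAV1, the coat protein of caveolae, at 0.63 and 0.44. The lowest were PLA2G4B at -0.88 and -0.84, the adhesion protein CD99L2 at -0.79 and -1.19, and the kinase CAMK1 at -0.47 and -0.49. CDH1, E-cadherin, was at -0.06 in MIA-PaCa2, where its level stayed at or under 0.173 TPM, and at 0.97 in PANC-1 (3.89 to 8.59 TPM). The epithelial marker EPCAM was at 0 TPM in the 3 MIA-PaCa2 libraries and at 0.18 in PANC-1. VIM, the mesenchymal filament protein, was at 0.02 and 0.17 and the repressor ZEB1 at -0.05 and 0.08. ENAH was at 0.05 and 0.14 and CTNND1 at 0.22 and 0.44. On simulated values with this design, limma recovered 0% of 1.5-fold, 63.5% of 2-fold and 88% of 4-fold gene changes. For transcripts the simulated changes were in the odds of a transcript within its gene, not in its level. Of these it recovered 0% at 2-fold, 0% at 4-fold and 40.5% at 8-fold.

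ESRP2 against LPCX over both lines gave changes of like size, with 65.1% of all tested genes positive and a median of 0.06. As with ESRP1, the fixed total of TPM means that this shift does not show a general rise. Splicing target genes were positive in 32 of 34 (median 0.16), cholesterol synthesis genes in 21 of 24 (median 0.16) and G1/S genes in 34 of 40 (median 0.12). HMGCS1 was at 0.37 in MIA-PaCa2 and 0.58 in PANC-1, and UNG at 0.69 and 0.44. Camera called these 3 of 26 lists, at adjusted p = 0.00678, 0.00953 and 0.0462. None of them held with the correlation estimated, at adjusted p = 0.857 with an estimated correlation for each. Again that version rests on 2 residual degrees of freedom, so the loss does not show its reason. In MIA-PaCa2 these lists lay nearer to random lists than in PANC-1, at percentile 85.3 against 98.5 for splicing targets, 45.7 against 100 for cholesterol synthesis (medians 0.02 and 0.33) and 77.99 against 99.95 for G1/S genes. The rank correlation of the ESRP2 ratios with transcript length was 0.349 in MIA-PaCa2 and 0.265 in PANC-1. Epithelial junction and identity genes were positive in 26 of 29 (median 0.12) and did not pass (adjusted p = 0.0886), and neither did the YAP and TEAD targets, 20 of 21 positive (median 0.18, adjusted p = 0.0840). Adjusted over the list alone, 4 epithelial genes rose, GRHL1 (0.94), the tricellular junction protein LSR (0.50), plakoglobin JUP (0.43) and the tight junction scaffold TJP1 (0.39). GRHL1 also rose among the splicing targets. In the same adjustment the genes that rose in other lists included 2 of cholesterol synthesis, with HMGCS1 (0.48) among them, the splicing regulator PTBP3 (0.52) and the neuronal adhesion gene L1CAM (0.41), and the exporter ABCC3 fell by 0.69 on the log2 scale.

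Over all genes limma called 1 gene higher and 1 lower for ESRP2. FLJ23867, an uncharacterised locus with no coding transcript in the table, rose by 2.05 (SE 0.107, 2 lines, adjusted p = 0.0281), from 1.59 to 9.16 TPM in MIA-PaCa2 and from 5.29 to 26.5 TPM in PANC-1. With ESRP1 it was at 5.75 and 16.9 TPM. SNORA63B, a small nucleolar RNA, fell by 2.19 (SE 0.122, adjusted p = 0.0281), from 20.02 to 3.32 TPM in MIA-PaCa2 and from 29.9 to 6.19 TPM in PANC-1. Ratios of small RNA entries spread more widely than those of coding genes at the same TPM. The SE of SNORA63B borrows in part from all genes at its level, so it may be too small. ESRP2 itself was at 5.32 (SE 1.11, adjusted p = 0.329), since its ratio was 7.53 in MIA-PaCa2 and 3.11 in PANC-1. An unadjusted p under 0.05 was found for 1634 genes. The calls ended without any 1 of MIA-PaCa2 LPCX, MIA-PaCa2 ESRP1, PANC-1 LPCX or PANC-1 ESRP1 (0 genes each), and became 30 genes without MIA-PaCa2 ESRP2 and 13 without PANC-1 ESRP2. Coding genes highest in both lines after GRHL1 (1.13 and 0.76) were the polymerase I factor RRN3 (0.70 and 0.62), the phosphatase DUSP9 (0.48 and 0.63) and the dynein heavy chain DYNC1H1 (0.48 and 0.54). The lowest were the ribosomal protein RPS29 (-0.72 and -0.75), PRKCA, protein kinase C alpha (-0.63 and -0.72), CD99L2 (-0.62 and -0.85) and CAMK1 (-0.71 and -0.60). ZEB1 was at 0.16 and 0.03, VIM at 0.03 and 0.19, EPCAM at 0.20 in PANC-1, ENAH at -0.10 and 0.23, and CTNND1 at 0.08 and 0.41.

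ESRP1 and ESRP2 were compared directly with the same model. Of 11829 genes only ESRP1 was called in limma (log2 8.53, SE 0.130, adjusted p = 5.29e-05), with 497 genes at an unadjusted p under 0.05. Without PANC-1 ESRP2 the count was 23, and without MIA-PaCa2 ESRP2 it was 9. Among transcripts limma called 0, with 582 at an unadjusted p under 0.05. Coding genes above ESRP2 in both lines with ESRP1 included the collagen COL5A2, the convertase inhibitor PCSK1N and RPS29, and those below included the spectrin repeat proteins SYNE2 and DST. SYNE2 was at -0.41 with ESRP1 and 0.37 with ESRP2 in MIA-PaCa2, and at 0.00 and 0.48 in PANC-1. Ratios to LPCX increased with transcript length more for ESRP2 than for ESRP1. The rank correlations were 0.349 against 0.0590 in MIA-PaCa2 and 0.265 against 0.231 in PANC-1. Whether the genes named here follow this trend was not tested. None of 26 lists passed. Metallothioneins, which bind zinc and copper, came closest, with 2 of 7 positive and a median of -0.29 (adjusted p = 0.0904).

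Within MIA-PaCa2, globin genes led the ESRP1 library. HBB was at 569 TPM against 0.675 with LPCX, HBA2 at 670 against 2.26, and HBA1 at 336 against 0.130, which together made 0.158% of that library's TPM. Of 28 genes of blood cells, 20 were highest in that library among the 3 of MIA-PaCa2, with a median of 0.764 TPM against 0.0692 with LPCX. Among other coding genes the collagenase MMP1 was 1.32 higher on the log2 scale, the cell cycle inhibitor CDKN1A 1.20 and the keratin KRT15 1.02. GHRL, the ghrelin gene, was at -2.37 with ESRP1 and -2.43 with ESRP2. With ESRP2 the highest coding genes included the tensin TNS4 (1.52), DDIT4L (1.49), the keratin KRT13 (1.34, and 1.13 with ESRP1) and the cytokine IL18 (1.37). The lowest were CARD16 (-2.41) and the receptor kinase ROR1 (-1.49). NF-kB, cytokine and chemokine genes had medians of 0.20 with ESRP1 and 0.25 with ESRP2, at percentiles 100 and 99.99 of random lists, with TRAF1 at 0.72 and 1.08 and CXCL5 at 0.50 and 1.003. Epithelial junction and identity genes had medians of 0.18 and 0.24 (percentiles 100 and 99.99). The mesenchymal list had medians of -0.03 and 0.01 (percentiles 3.15 and 41.6). Cholesterol synthesis genes had medians of 0.15 and 0.02 (percentiles 99.96 and 45.7) and G1/S genes of 0.06 and 0.06 (percentiles 77.6 and 77.99). In all, 58 genes were at least 2-fold higher and 80 lower of 10787 with ESRP1, and 88 higher and 88 lower of 10893 with ESRP2. Small RNA entries made up 39 and 69 of these with ESRP1 and 65 and 63 with ESRP2, and genes with a coding transcript 17 and 5, and 13 and 19.

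Within PANC-1 several coding genes had large ratios with both proteins. ANKRD1, a target of YAP and TEAD, was at 1.28 with ESRP1 and 1.34 with ESRP2, FGFR2, a growth factor receptor that ESRPs splice, at 1.08 and 0.69, CDH1 at 0.97 and 0.71, and desmoplakin, DSP, at 0.91 and 0.48. The recombinase DMC1 was at 1.16 and 1.18. Lower were EPHB6, an ephrin receptor, at -0.97 and -1.61 (245, 124 and 79.2 TPM with LPCX, ESRP1 and ESRP2), the calcium channel TRPV6 at -1.02 and -1.69, CNIH3 at -1.03 and -1.55, the esterase CES1 at -0.64 and -2.04 and the collagen COL13A1 at -0.95 and -1.42. Cholesterol synthesis genes had medians of 0.28 and 0.33 (percentiles 100 and 100) and G1/S genes of 0.21 and 0.21 (percentiles 100 and 99.95), where the median of all genes was 0.09 with ESRP1 and 0.10 with ESRP2. Epithelial junction and identity genes had medians of 0.17 and 0.17 (percentiles 99.1 and 97.5) and the mesenchymal list 0.08 and 0.02 (percentiles 51.6 and 15.6). NF-kB, cytokine and chemokine genes had medians of -0.02 and -0.05 (percentiles 1.15 and 0.5), and integrins and basement membrane genes -0.01 and -0.04 (percentiles 2.12 and 1.42). At least 2-fold, 41 genes were higher and 127 lower of 11135 with ESRP1, and 42 higher and 176 lower of 11140 with ESRP2. Small RNA entries, whose median ratios were -0.48 and -0.66, made up 117 of the 127 and 150 of the 176, and genes with a coding transcript 7 higher and 4 lower with ESRP1 and 12 and 15 with ESRP2.

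Few genes passed 2-fold in both lines, and nearly all were small RNA entries. With ESRP1 there were 4 higher and 13 lower (0.0616 and 0.401 for independent lines) and 9 in opposite directions (0.381). With ESRP2 there were 9 higher and 18 lower (0.139 and 0.675) and 19 in opposite directions (0.804). The values for independent lines treat all genes alike, although the ratios of small RNA entries spread more widely. They are therefore too low for such entries, and counts above them do not show that the lines agree. Among those in the same direction, the coding gene was the introduced ESRP1 or ESRP2 alone. Of the small RNAs, the microRNA entry MIR7110 was at 2.80 and 1.22 with ESRP1 and 2.94 and 1.92 with ESRP2 in MIA-PaCa2 and PANC-1. SNORD104 was at -2.10 and -1.44 with ESRP1, and SNORA9B at -2.89 and -2.47 with ESRP2. Across genes, which are not independent replicates, the ratios of the 2 lines had r = 0.265 and rank correlation 0.223 for ESRP1 (9876 genes), and 0.166 and 0.240 for ESRP2 (9926 genes). Over a set of 11121 genes the rank correlations were 0.202 for ESRP1 and 0.219 for ESRP2. Between constructs they were 0.246 for MIA-PaCa2 ESRP1 with PANC-1 ESRP2 and 0.168 for MIA-PaCa2 ESRP2 with PANC-1 ESRP1. The likeness of the lines was thus of similar size within and between constructs. All of these correlations use the same LPCX library of each line. A difference common to both LPCX libraries would enter each of them, so they do not show a response to the proteins.

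The other lists gave no call over both lines in camera, with adjusted p given here for ESRP1 and then ESRP2. Interferon response genes were positive in 31 of 40 with either protein (0.230 and 0.339), p53 targets in 19 and 15 of 22 (0.173 and 0.721) and G2/M genes in 44 and 41 of 56 (0.230 and 0.390). TGF-beta response genes were positive in 17 and 22 of 26 (0.883 and 0.522) and mesenchymal and EMT genes in 12 and 9 of 19 (0.596 and 0.358). Genes of FGF and ERBB receptors and ligands had 0.907 and 0.390, ERK pathway output 0.510 and 0.353, integrins and basement membrane 0.596 and 0.358, and extracellular proteolysis and invasion 0.726 and 0.952. NF-kB, cytokines and chemokines had 0.979 and 0.678, immediate early and heat shock genes 0.230 and 0.808, NRF2 and oxidative stress genes 0.919 and 0.295, and the unfolded protein response with ATF4 targets 0.230 and 0.295. Splicing factors and RNA-binding proteins had 0.231 and 0.663, metallothioneins 0.231 and 0.390 and replication-dependent histones 0.596 and 0.403. Hypoxia and glycolysis genes had 0.154 for ESRP2 and YAP and TEAD targets 0.119 for ESRP1. Genes of the classical subtype of pancreatic cancer had 0.883 and 0.752 over 3 measured members, and those of the basal-like subtype 0.907 and 0.569 over 9.

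Markers of other cell types were low. The median leukocyte marker was at 0.338 TPM in MIA-PaCa2 LPCX, 0.563 with ESRP1 and 0.2503 with ESRP2, and at most 0.190 TPM in PANC-1. LAPTM5 was the highest in MIA-PaCa2, at 125, 85.8 and 134 TPM, and CD68 in PANC-1, at 295, 315 and 364 TPM (camera over both lines, adjusted p = 0.907 and 0.789). Of 30 acinar and islet markers, SCG2 alone reached 5 TPM, in MIA-PaCa2, at 146, 143 and 80.3 TPM. Of 17 fibroblast and endothelial markers, COL1A2 alone reached it in MIA-PaCa2 (132, 122 and 124 TPM) and COL1A1 alone in PANC-1 (66.4, 108 and 93.1 TPM). Among 20 neuronal markers 4 reached it in MIA-PaCa2 and 5 in PANC-1, led by the tubulin TUBB3 (camera, adjusted p = 0.510 and 0.453). None of the 13 mitochondrially encoded genes is in the table.

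The ESRP1 and ESRP2 responses within a line share 1 LPCX library, which by itself makes them alike. In PANC-1 their correlation across 11121 genes was r = 0.740, where 0.4996 was simulated for unchanged groups sharing a control, with covariances of 0.0623 measured and 0.0350 simulated. In MIA-PaCa2 it was 0.281, where 0.495 was simulated, with covariances of 0.0205 and 0.0345. Part of either value may come from the shared control. The simulation takes 1 spread per gene from all 6 libraries, so it cannot represent an LPCX library that varies more than the others. Over 10259 genes with a coding transcript the values were 0.780 in PANC-1 (covariance 0.0304, 0.0206 simulated) and 0.202 in MIA-PaCa2 (0.00918, 0.0197 simulated).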

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

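The tests of whether ESRP1 raises globins in either line, of more small RNA in the PANC-1 LPCX library, and of the shared LPCX library as the whole cause were chosen after the result was seen.

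Some named genes moved in opposite directions in the 2 lines by at least 2-fold, and none of these differences was tested. With ESRP1 the log2 ratios in MIA-PaCa2 and PANC-1 were 3.20 and -1.22 for MIR616, 1.37 and -3.52 for SNORA75, and 1.03 and -1.46 for SNORD18B. With ESRP2 they were 3.56 and -3.23 for MIR6813, 3.95 and -4.04 for RNVU1-7, -1.19 and 3.22 for SNORA80B, 1.21 and -4.37 for SNORD18B, 3.88 and -1.52 for SNORD57, and -3.63 and 1.28 for SNORD60. Among coding genes with ESRP2 they were -1.32 and 1.31 for the chemokine receptor CXCR4, 1.09 and -1.30 for the histone gene HIST1H4E, and -1.41 and 1.15 for SERF1A.

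Globin transcripts stood out in the MIA-PaCa2 ESRP1 library, with HBA1, HBA2 and HBB summing to 1575 TPM there and 3.06 TPM in MIA-PaCa2 LPCX. An effect of ESRP1 in either line is argued against by PANC-1 ESRP1, where the 3 globins summed to 1.40 TPM against 2.11 TPM in PANC-1 LPCX. RNA of blood cells is a candidate source: of 28 blood-cell genes listed before the test, 20 were highest in MIA-PaCa2 ESRP1 of the 3 MIA-PaCa2 libraries (exact binomial test, two-sided, p = 5.43e-05), among them the neutrophil genes FCGR3B at 3.67 TPM, MNDA at 1.57 TPM and CSF3R at 1.32 TPM. The test takes the 28 genes as independent, although they may vary together. With 1 library per group, its p-value does not measure the spread between libraries. HBD was at 0 TPM in each library and PTPRC at 0.563 TPM in MIA-PaCa2 ESRP1, and the share of blood-cell RNA was not estimated. An effect of ESRP1 on globins in MIA-PaCa2 alone was not tested and stays open.

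Small RNA entries led the counts at 2-fold, although the kit selects polyadenylated RNA. Few reads on short entries may account for their spread: the standard deviation of their ratios was at least 4.67 times that of coding genes at the same TPM in each of the 4 comparisons. Their lower values in PANC-1 may also reflect more small RNA in the PANC-1 LPCX library, since their median log2 ratio was -0.48 with ESRP1 and -0.66 with ESRP2, where coding genes had 0.09 and 0.11. No biological explanation was tested, and a lower level of these RNAs with either protein in PANC-1 stays open.

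ESRP1 and ESRP2 responses were alike in PANC-1, above the value simulated for a shared control, while those in MIA-PaCa2 lay below it. The shared LPCX library as the whole cause was examined with the mean PANC-1 and mean MIA-PaCa2 responses, which have no library in common. Their rank correlation was 0.286 (0.218 after removal of a length and GC trend). Variation of the PANC-1 LPCX library alone would not give this, but a difference common to both LPCX libraries would. The correlation therefore does not decide how much of the likeness within PANC-1 comes from its LPCX library. Removal of a trend with transcript length and GC content took the PANC-1 covariance from 0.0299 to 0.0264 (SE 0.000768) on 9314 genes. Most of the covariance was thus left without the trend. It stayed above the 0.0195 simulated for a shared control on these genes after the same removal. In MIA-PaCa2 the covariance was 0.00890 (SE 0.00253), below the simulated 0.0195. The simulation takes 1 spread per gene from all 6 libraries, so it cannot represent an LPCX library that varies more than the others. These covariances therefore do not decide whether the trend and the shared control together account for the likeness in PANC-1. A response common to both proteins is a hypothesis, and a PANC-1 LPCX culture that differed from the others for another reason stays open.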

How the results depend on the processing

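The tests with genes with an NM transcript, median ratio scaling in the model over both lines, the steps of 10 and 20 points, gene totals of 20 and 50 TPM, the transcript model over both lines with its alternatives, and the counts of cassette exons were chosen after the data were seen; the other alternatives, the gene lists and the 2-fold threshold were set before the data were examined. Counts at 2-fold in 1 line (138 for MIA-PaCa2 ESRP1, 168 for PANC-1 ESRP1, 176 for MIA-PaCa2 ESRP2, 218 for PANC-1 ESRP2) became 75, 94, 109 and 142 with a pseudocount of 5, 387, 474, 479 and 523 with a floor of 1 TPM, 28, 57, 52 and 73 with a floor of 20 TPM, and 22, 11, 32 and 27 among genes with an NM transcript. In both lines the 17 genes for ESRP1 and 27 for ESRP2 became 4 and 14 with a pseudocount of 5, 74 and 79 with a floor of 1 TPM, 4 and 5 with a floor of 20 TPM, 59 and 78 at 1.5-fold, and 1 and 1 among genes with an NM transcript. Median ratio scaling gave 145, 176, 183 and 224 in 1 line and 20 and 31 in both. Genes called over both lines (1 for ESRP1, 2 for ESRP2, 1 for ESRP1 against ESRP2) became 0 in each contrast without the filter or without the block, and 0 for ESRP2 with a pseudocount of 0.1 or among genes with an NM transcript. Leaving out 1 library at a time gave 1 to 1 for ESRP1, 0 to 30 for ESRP2 (30 without MIA-PaCa2 ESRP2, 13 without PANC-1 ESRP2, 0 without any other 1) and 1 to 23 for ESRP1 against ESRP2 (9 without MIA-PaCa2 ESRP2, 23 without PANC-1 ESRP2). These fits have 1 residual degree of freedom, and the lone library of a construct is assumed to vary like the others. The 1 transcript called for ESRP1 became 0 with gene totals of 1 TPM, a pseudocount of 0.1 TPM, no block or any 1 library left out (0 to 0), and 2 with gene totals of 20 TPM, where ESRP2 had 4. Transcripts moved in both lines (236 for ESRP1, 311 for ESRP2) became 40 and 47 at 20 points, and 450 and 573, 75 and 116, and 25 and 45 with gene totals of 1, 20 and 50 TPM. Cassette exons (49 and 71) became 14 and 20 at 20 points, 78 and 107 with gene totals of 1 TPM, and 27 and 41 with gene totals of 20 TPM. The 8 list calls were lost with an estimated correlation (adjusted p = 0.918 for the 5 of ESRP1 and 0.857 for the 3 of ESRP2), and the other 70 list results kept their side of the threshold. With 2 residual degrees of freedom that version could hardly call a list, so the loss does not show that correlation made the calls. Of 3220 alternative values of named genes, 2909 stayed close and 311 moved. Among ratios of at least 2-fold 0 changed sign, and sign changes of smaller ratios were not counted. Higher floors and gene totals let fewer genes or exons enter and a step of 20 points is a stricter threshold. A floor or gene total of 1 TPM lets more enter, 1.5-fold is a looser threshold, and a pseudocount of 5 makes ratios smaller. Genes with an NM transcript leave out the small RNA entries, which made up most of the 2-fold counts. The cause of the other shifts was not tested. The alternatives for read counts (size factors and count models) were not run, since TPM hold no counts, and limma with a trend, listed as an alternative, became the main model. With 2 lines per construct, splits of the samples into other groups were not counted.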

Other observations

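The tests of endogenous ESRP2, of the reading frame and of paralog differences were chosen after the result was seen, while that of a raised copy number was written before the genes it used were read.

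Values of further groups are given here for each line. Replication-dependent histones had medians of 0.22 with ESRP1 and 0.03 with ESRP2 in MIA-PaCa2 (percentiles 99.99 and 28.5), and -0.15 and 0.01 in PANC-1 (percentiles 0.3 and 16.8). P53 targets had medians of 0.18 and 0.04 in MIA-PaCa2 (percentiles 100 and 40.5), and 0.11 and 0.10 in PANC-1. Metallothioneins had medians of -0.31 and 0.24 in MIA-PaCa2 and 0.21 and 0.36 in PANC-1, with MT1X at -0.31 and 0.55, and -0.40 and -0.09. Genes of the unfolded protein response and ATF4 had medians of 0.03 and -0.02, and 0.05 and 0.01, with PHGDH, the first enzyme of serine synthesis, at -0.55 and -1.04 in PANC-1. The list of FGF and ERBB receptors and ligands had medians of 0.04 and 0.18, and 0.18 and 0.19, and the epiregulin gene EREG was at -0.32 and -0.68 in PANC-1. No difference between the lines was tested.

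Whether the exons that moved in all 4 comparisons tend to keep the reading frame was left undecided. Of 27 coding exons, 23 (85.2%) had a length divisible by 3, against 1100 of 1789 other coding cassette exons (61.5%, Fisher's exact test, two-sided, p = 0.0149). Exons of 1 gene are not independent, and CD44 alone gave 8 of the 28. Without CD44 it was 15 of 19 (p = 0.156), and with 1 coding exon per gene 14 of 17 against 789 of 1218 (p = 0.199, both by Fisher's exact test, two-sided), so the call over all exons depends on CD44.

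ESRP1 and ESRP2 differed by at least 10 points in both lines on 48 exons of 37 genes. The hypothesis that the paralogs differ in the same way in both lines was left undecided: 24 of the 37 genes went the same way (exact binomial test, two-sided, p = 0.0989). Over exons, which are not independent within a gene, 34 went the same way and 14 the opposite way (6.97 and 7.40 for independent lines, exact binomial test, two-sided, p = 0.00552). The test was stated on exons and passes there, and it does not pass with 1 exon per gene. Inclusion was further from LPCX with ESRP2 in both lines in 15 genes, with ESRP1 in both in 6, and the lines differed in 16. The former included MYOF, USO1, BAIAP2, MAP3K7, RAC1 and PTPRF and the latter ECT2, ZNF142 and CACFD1, named after their values were seen. The MAP3K7 exon (GRCh38 chromosome 6, 90544552 to 90544632, coding) was at 31.2%, 40.7% and 68.9% in MIA-PaCa2 and 12.5%, 17.5% and 29.2% in PANC-1, with LPCX, ESRP1 and ESRP2.

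PANC-1 holds ESRP2 before overexpression, so its LPCX exons might lie nearer the ESRP side. Of 73 genes with an exon moved in both PANC-1 comparisons, 29 had PANC-1 LPCX on the ESRP side of MIA-PaCa2 LPCX (exact binomial test, two-sided, p = 0.101). The hypothesis cannot be told apart from no shift with these exons, since choosing exons that moved in PANC-1 favours those with room left to move. DNM2 at 67.1% against 15.3% lay on the ESRP side.

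A block of genes on chromosome 19 was far higher in PANC-1 than in MIA-PaCa2 before overexpression. AKT2, a kinase of the insulin pathway, was 4.21 higher on the log2 scale and PAF1, a transcription elongation factor, 4.76. A raised copy number of the interval in PANC-1 is a candidate explanation: 36 genes within 1 Mb of RPS16 that had not been looked at had a median of 3.04, against -0.14 for 693 other genes of the chromosome. An unbroken run of 20 genes at 4-fold or more spans 39342396 to 40285536 (GRCh38), from SAMD4B to AKT2. Copy number itself was not measured.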
